A study of Mus musculus with 12 samples.

How the data were processed

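Gene expression was measured in mouse yolk sacs, the extraembryonic membrane that makes the first blood cells and vessels and feeds the early embryo. The design had 4 groups of 3 arrays: wild type and Norrin yolk sacs at embryonic day 8.5 (E8.5) and at E10.5. Norrin is a secreted ligand of the receptor Frizzled4 and signals through beta-catenin; in the Norrin groups (Z/Norrin mice) it was made ectopically from a conditional over-expression allele. Per the labels, each sample pooled the yolk sacs of 3 to 5 embryos of mixed sex on a mixed C57Bl6/129 background, and total RNA was extracted with Trizol and RNeasy and labelled with biotin. The replicates are therefore separate pools, and no litter, batch or hybridisation day was given. The Cre driver and the time of activation were not given in the sources used here.

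The authors deposited 1 column of log2 expression values per array, made with RMA, per the submitters' processing notes, which name no version. RMA corrects the background, quantile-normalizes the arrays and summarises the probes of each probe set by median polish on the log2 scale. The array was the Affymetrix Mouse Genome 430 2.0, and the table held 45101 probe sets on 12 arrays with no columns of other samples. The median of the deposited log2 values lay between 6.62 and 6.73 in wild type E8.5, 6.59 and 6.67 in Norrin E8.5, 6.97 and 6.98 in wild type E10.5, and 6.99 and 7.01 in Norrin E10.5. Every pair of arrays within a stage held 26 to 93 identical values, and the 36 pairs across stages held 0. Similarity does not account for this: the least alike pair within a stage (r = 0.967) held 27, and the most alike pair across stages (r = 0.970) held 0. Arrays quantile-normalized together share 1 set of values before summarisation, so each stage went through RMA in its own run. Comparisons within a stage do not rest on this. Comparisons between stages do, since stage and run cannot be told apart, and their split of higher and lower calls is given under other scalings too. Hybridisation spike-ins (9 control probe sets) had mean log2 values of 12.38 and 12.36 in the wild type and Norrin replicates 3 at E8.5, 10.95 to 11.33 in the other 4 E8.5 arrays and 11.15 to 12.06 at E10.5. With arrays no read depth exists; the number of arrays limits the precision.

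Probe sets were named from the platform annotation table: 34945 had 1 gene, 932 several and 9160 were unnamed here. Of the named ones, 34741 matched the RefSeq gene table by gene ID, and 0 symbols needed an update. Positions are those of the RefSeq genes on mouse build GRCm38.p6, not of the probes. The 64 control probe sets and those with no or several genes were left out. Where a gene had more than 1 probe set (9010 genes), the one with the highest mean over all 12 arrays was used, which left 18193 genes. Where another probe set gave under 70% of the change of a gene named by the rule below and past the threshold, its value is given with the gene.

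The main test was limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with default settings) on the deposited log2 values, in a model with 1 mean per group over all 12 arrays (8 residual and 4.17 prior degrees of freedom). It gave 5 contrasts: Norrin minus wild type at E8.5 and at E10.5, the difference of these effects (interaction), and E10.5 minus E8.5 in each genotype. Tests were two-sided with Benjamini-Hochberg adjustment over the genes of a contrast and a threshold of 0.05. All adjusted p-values of genes in the text are from limma unless another tool is named.

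The tests, the gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule named Ndp (the Norrin gene), Fzd4, Lrp5, Lrp6 and Tspan12. In the Norrin contrasts, the interaction and the wild type stage contrast it named up to 10 genes per direction with the largest log2 change among those past the threshold, with non-overlapping groups (not for the interaction) and a mean in the higher group at or above the median gene level of 7.68. From each fixed list it named up to 4 members with the largest change per Norrin contrast. Riken clones and predicted genes could be passed over.

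There were 27 fixed lists: Norrin receptor complex, Wnt beta-catenin targets, Wnt pathway components, barrier endothelial genes, pan-endothelial, arterial and Notch, venous and lymphatic, angiogenic signals, smooth muscle and pericyte, erythroid, hematopoietic progenitor, megakaryocyte, macrophage and myeloid, visceral endoderm, parietal endoderm, trophoblast, decidua, embryo neural, extraembryonic mesoderm and mesenchyme, BMP and TGF-beta targets, hypoxia, proliferation, p53 targets, stress response, interferon, cholesterol synthesis and sex-linked genes. The trophoblast, decidua and embryo neural lists stand for tissues that a dissected yolk sac could carry along. The parietal endoderm list was not set among these, and its share in the pools was not tested. Each list was counted gene by gene, over all genes tested and adjusted over the list alone. The 26 lists with at least 5 measured genes were tested with limma's camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation (statmod 1.5.0) and with fry, each adjusted over the lists of a contrast. Camera compares a list with all other genes; fry asks whether its members move, on balance, one way.

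The replicate numbers in the labels are shared between the groups. Within a stage the numbers paired the arrays by a rule set beforehand (every pair above 0.1): the deviations of same-numbered pools from their group means correlated across genes at r = 0.73, 0.32 and 0.73 at E8.5 and at 0.51, 0.21 and 0.22 at E10.5. Differently numbered pools of the 2 genotypes ran from -0.72 to 0.30 at E8.5 and from -0.35 to 0.16 at E10.5. The lowest same-numbered values, both of number 2, thus lay close to the highest of these. The labels do not say what a number stands for. Across stages the numbers did not pair, with negative correlations among them. The fit with the number as a block within each stage (4 residual degrees of freedom) was added after seeing the data, and its value stands beside a result where it changed a call or moved a count by over 1.5 times.

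The script was tested on simulated data with 200 of 18193 genes changed. In the Norrin contrast at E8.5, limma without the block recovered 12% of genes changed by 0.5 (log2), 74% at 1, 96% at 2 and 100% at 3, with 7 false calls; at E10.5 it recovered 20%, 76%, 94% and 98%, with 9 false calls. For wild type with stage the shares were 10%, 72%, 98% and 98%. With the block, on data simulated with a part shared by same-numbered pools, recovery at 0.5 was 42% at either stage. The fits without the block were run on data without such a part, so these shares do not measure a gain from blocking. Raising the hypoxia list by 0.7 gave a call for it and for 1 of 23 other lists. The simulated genes varied independently, so this does not show how often preset camera calls lists of correlated genes.

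The alternatives set beforehand were a filter on dim genes, all probe sets, the mean of a gene's probe sets, probe sets marked as cross-hybridising left out, quantile normalization, median centring, cyclic loess, a floor at the 25th percentile, trended robust spread, array weights, only the 6 arrays compared, the replicate number as a block, a 2-fold threshold and each array left out in turn. Added after seeing the data were the block within each stage, both pools of Norrin number 2 left out, and the trophoblast mean, Prl8a2 or the mean of the Y-linked genes Eif2s3y, Kdm5d and Uty as a covariate. Probe sets with no or several gene names entered only the fit of all probe sets, where their calls were also counted separately.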

Results

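Transcripts of whole yolk sac were profiled at E8.5 and E10.5 on 12 arrays, 3 per group, from wild type embryos and from embryos with ectopic Norrin (Z/Norrin mice, called Norrin here). The median log2 value per array ranged from 6.59 to 6.73 at E8.5 and from 6.97 to 7.01 at E10.5. Within a group, the 3 arrays correlated across genes at r = 0.975 to 0.992, and no array was a copy of another. The median standard error of a Norrin effect was 0.16 (log2) over 18193 genes. The series asks what Norrin and Frizzled4 signalling does to gene expression in the yolk sac, so each stage was compared with its own wild type, then the stages with each other. On mouse build GRCm38.p6 the RefSeq genes described in most detail lie on chromosome 1 at 4490928 to 4497426 (Sox17), 19 at 37697738 to 37701536 (Cyp26a1), 14 at 68083863 to 68089095 (Nefl), 7 at 35119293 to 35121928 (Cebpa), 8 at 84901982 to 84905291 (Klf1) and 5 at 147561604 to 147726438 (Flt1).

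Transcripts of the Norrin receptor complex were measured at both stages, with no change past the threshold. Fzd4, the Norrin receptor, had a log2 level of 9.28 ± 0.47 (SD, n = 3) in wild type and 9.41 ± 0.38 in Norrin at E8.5, and of 10.01 ± 0.18 and 9.94 ± 0.17 at E10.5. The Norrin effects of its coreceptors Lrp5, Lrp6 and Tspan12 were -0.02, -0.29 and 0.07 at E8.5. At E10.5 they were -0.48, -0.14 and 0.07, with an adjusted p of 0.101 for Lrp5 (0.013 with replicate number as a block within the stage). Of the 5 genes in the complex, 0 passed the threshold by limma at either stage (0 and 1 at an unadjusted p under 0.05), and by camera the list had an adjusted p of 0.749 at E8.5 and 0.334 at E10.5. Ndp itself lay near the floor of the array in every group, at 4.59 ± 0.10 and 4.54 ± 0.09 at E8.5 and at 4.49 ± 0.06 and 4.49 ± 0.05 at E10.5. Whether its single probe set covers the transgene was not given, so this value checks nothing about the labels.

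At E8.5, ectopic Norrin raised a small set of genes by large factors. Nefl, the neurofilament light chain, was 7.64-fold higher (log2 2.93, SE 0.33, adjusted p = 0.0065), and Nefm, the medium chain, 4.6-fold higher. Sox17, a transcription factor of endoderm and arterial endothelium, rose from 8.03 ± 0.90 to 10.75 ± 0.15 (SD, n = 3; adjusted p = 0.017). Cyp26a1, the enzyme that degrades retinoic acid, rose from 8.43 ± 0.56 to 10.96 ± 0.34 (adjusted p = 0.0098). Among lower genes were Apoa4, an apolipoprotein made by visceral endoderm, at 13.21 ± 0.03 in wild type and 12.03 ± 0.07 in Norrin, and Slc40a1, the iron exporter ferroportin, at 11.60 ± 0.14 and 10.51 ± 0.17.

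In all, limma called 14 genes at E8.5, 10 higher and 4 lower, and 1314 genes had an unadjusted p under 0.05. In all 14 the 3 Norrin pools lay apart from the 3 wild type pools; chance gives this for 10% of genes, and it held for 2167 of the 18193. The other higher genes were Flrt3, a membrane protein with leucine-rich repeats (2.11, adjusted p = 0.0449), carboxypeptidase Cpm (1.83), Prom1 (1.71, adjusted p = 0.00056), Msx2 (1.71, adjusted p = 0.039), Zfp703 (1.26) and Scube2 (1.01). The cation transporter Slc22a2 fell by 1.68. The last lower call, Tcim, fell by 1.94. It lay under the level rule and was named after its values were seen. For Msx2 a second probe set gave -0.06, and for Zfp703 the other 2 gave 0.03 and 0.23. With replicate number as a block within the stage, 257 genes passed, 146 higher and 111 lower, among them all 14. With array weights 5147 passed (2440 higher, 2707 lower) and with replicate number as 1 block across both stages 5. With arrays centred on their median 11 passed, 9 higher and 2 lower. A fit to the 6 E8.5 arrays alone called 0 genes by limma (951 at an unadjusted p under 0.05), and without Norrin E8.5 replicate 2 only 1 was called.

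No gene list was called at E8.5. Camera called 0 of 26 lists at the preset correlation (lowest adjusted p = 0.0502, parietal endoderm, median 0.34), with 10 lists at an unadjusted p under 0.05, 0 with an estimated correlation and 0 by fry. With the block within the stage, macrophage and myeloid genes were lower (median -0.21, 0 of 19 members above 0, camera adjusted p = 0.0068) and proliferation genes higher (median 0.11, adjusted p = 0.034), and each had an adjusted p of 0.667 with an estimated correlation. Among 19 Wnt beta-catenin targets 0 passed by limma over all genes, 4 at an unadjusted p under 0.05 and 2 adjusted over the list alone (camera adjusted p = 0.0652). The 2 members with the largest effects were Dkk1, a secreted Wnt antagonist that is itself a target (1.18, adjusted p = 0.234; 0.022 with the block), and Axin2, a negative feedback regulator (1.07, adjusted p = 0.0701; 0.039 with the block). Among 30 Wnt pathway components the largest change was in Frzb, a secreted Wnt binder (1.02, adjusted p = 0.0933; 0.030 with the block), with 1 member adjusted over the list alone and 5 at an unadjusted p under 0.05. Among 16 mesenchyme genes Pdgfra had an effect of 1.54 (adjusted p = 0.171; 0.031 with the block), with 2 members adjusted over the list alone. Msx2 was the 1 called gene of 10 BMP and TGF-beta targets (2 adjusted over the list alone), and Sox17 the 1 called gene of the barrier (1 higher and 2 lower adjusted over the list alone) and of the arterial lists (1 and 1). By fry's test of change in either direction 7 of 26 lists passed.

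Visceral endoderm genes included the abundant secreted proteins of the yolk sac. Of 28 measured at E8.5, 1 fell (Apoa4), or 2 rose and 5 fell adjusted over the list alone. Afp went from 14.47, at the top of the scale, to 13.42, so its change may be understated (adjusted p = 0.234; 0.0215 with the block), and the fibrinogen chain Fga from 11.50 to 10.07 (adjusted p = 0.331; 0.0042 with the block). The list's median was -0.09 (camera adjusted p = 0.104). Trophoblast markers were high in 1 pool: the median of 10 trophoblast genes lay 1.38 above the wild type mean in Norrin E8.5 replicate 2 and between -0.18 and 0.07 in the other 5 pools. The Y-linked genes were low in Norrin E8.5 replicate 1 (mean 4.15, against 5.35 to 6.90 in the others).

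By E10.5 the Norrin yolk sacs differed from wild type in 741 genes, 337 higher and 404 lower. Pga5, a pepsinogen precursor, was 11.6-fold higher (8.17 ± 0.15 to 11.70 ± 0.48; adjusted p = 0.00079). Cyp26a1 and Sox17 were 8.3-fold and 7.84-fold higher. By preset camera erythroid and visceral endoderm genes were lower and hypoxia-responsive, parietal endoderm, Wnt pathway and angiogenic genes higher. Preset camera called 16 of 26 lists and fry 12, and camera with an estimated correlation called 0 (lowest adjusted p = 0.0515 with an estimated correlation). Cebpa, a transcription factor of liver and myeloid cells, was 7.95-fold lower (10.77 ± 0.25 to 7.78 ± 0.48; adjusted p = 0.00059).

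**Figure D1:**
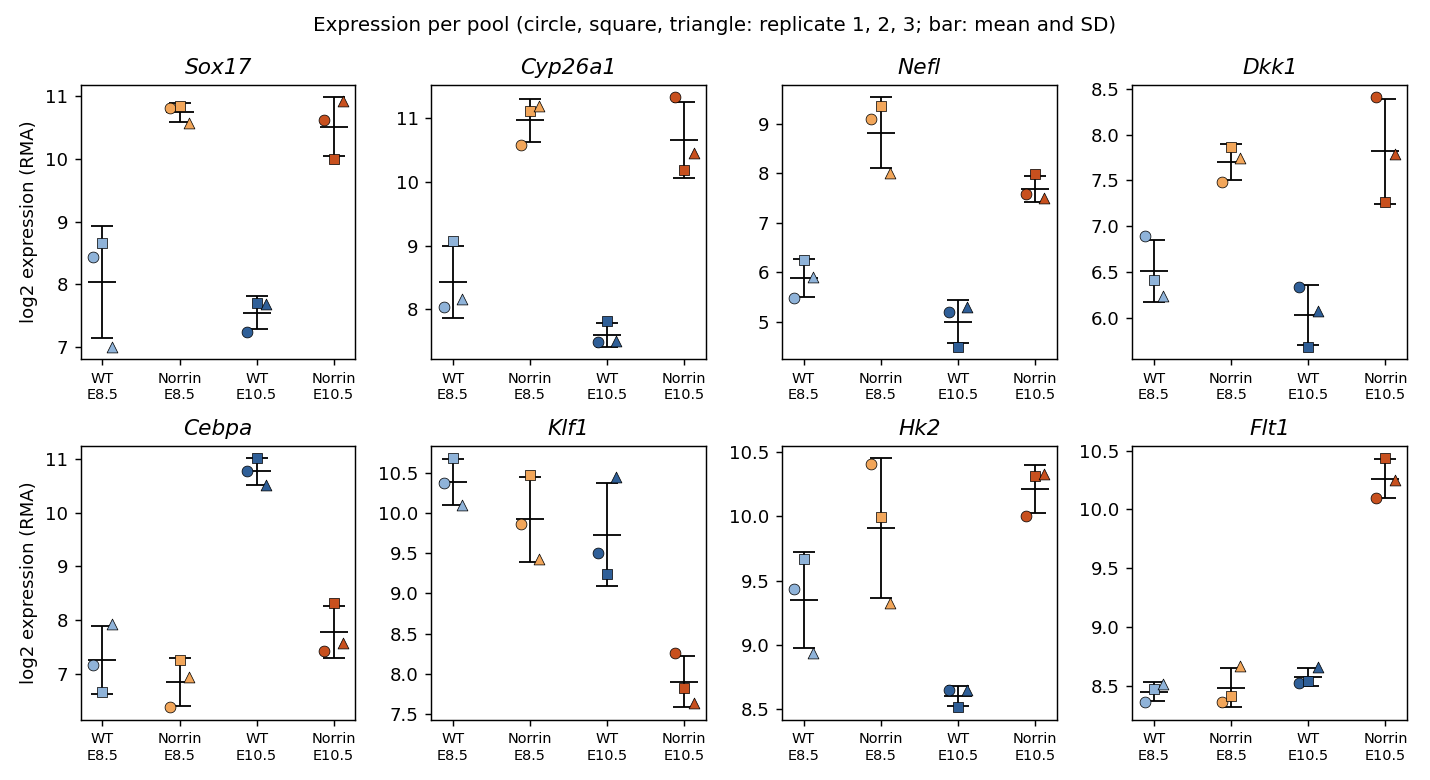
Log2 expression (RMA) of 8 genes in each pool, by genotype and stage; points are pools and bars the mean and SD of 3. Sox17, Cyp26a1 and Nefl lay higher in every Norrin pool at either stage, and the mean of Flt1 was 8.45, 8.48 and 8.57 in the first 3 groups and 10.26 in Norrin E10.5.

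Of the 741 genes, 333 changed at least 2-fold (138 higher, 195 lower), and 2555 genes had an unadjusted p under 0.05. In each of the 741 the 3 Norrin pools lay apart from the wild type pools, as they did in 4166 of 18193 genes. Other genes with large changes on the higher side were the serine protease Prss12 (2.98), Retreg1 (6.95-fold), Nefl (2.68, from near the floor at 5.00), the water channel Aqp8 (2.64), Igfbp1 (2.52, adjusted p = 0.0398), Flrt3 (2.47) and the parathyroid hormone receptor Pth1r (2.45). On the lower side were Fbp2, a fructose bisphosphatase of gluconeogenesis (-3.08), Saa4, a serum amyloid protein (-2.88, SE 0.15, adjusted p = 3.1e-06), Clca1 (-2.79), the tyrosine-degrading enzyme Hgd (-2.73), the efflux pump Abcb1a (-2.68), alcohol dehydrogenase Adh1 (-2.68), Serpina1c (-2.65), the kinase Sgk2 (-2.58) and Plet1os (-2.57). Second probe sets gave 1.60 for Retreg1, 1.54 for Nefl, -1.79 for Saa4, -0.18 for Clca1 and -0.13 for Hgd. With replicate number as a block within the stage 2400 genes passed, 1163 higher and 1237 lower, all 741 among them, and with array weights 2316. With 1 array left out the count ran from 353 (without Norrin E10.5 replicate 3) to 894.

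Erythroid genes were lower at E10.5. Of 23 measured, 13 fell over all genes and 20 adjusted over the list alone, 0 had a positive effect, and the median was -1.17 (camera adjusted p = 7.0e-20; adjusted p = 0.082 with an estimated correlation; fry adjusted p = 0.0045). They included the transcription factors Klf1, which fell from 9.73 to 7.90 (adjusted p = 0.0073), Tal1 (-1.65, adjusted p = 0.0227) and the nuclear protein Hemgn (-2.08, adjusted p = 0.0213). The blood group protein Rhag had an effect of -2.02 (adjusted p = 0.0586; 0.0016 with the block). The embryonic globins Hbb-bh1 and Hba-x fell by 0.58 and 0.57, and Hbb-y gave -0.10 (adjusted p = 0.946); in wild type these 3 lay at 14.43 to 14.61, at the top of the scale. The median fell in each Norrin pool, to -1.16, -1.06 and -1.37 against the wild type mean, where wild type pools ran from -0.41 to 0.49.

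Among other blood lists, single genes passed. Of 12 progenitor genes 1 rose, the stem cell factor receptor Kit (7.22 to 9.10, adjusted p = 0.0033; 1.10 by its other probe set); the median was -0.04 (camera adjusted p = 0.734). Of 9 megakaryocyte genes 1 fell, the integrin Itga2b (-0.45, adjusted p = 0.0475), with a median of -0.27 (camera adjusted p = 0.0347; adjusted p = 0.445 with an estimated correlation; 0.352 by preset camera without Norrin E10.5 replicate 1). Of 19 macrophage and myeloid genes 2 fell, Cebpa and the Fc receptor Fcgr3 (-1.98, adjusted p = 0.0118), and the list was not called (median -0.11, camera adjusted p = 0.0539).

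Hypoxia-responsive genes rose. Of 24 measured, 9 rose over all genes and 18 adjusted over the list alone, 0 fell, and the median was 0.74 (camera adjusted p = 1.8e-16; adjusted p = 0.0515 with an estimated correlation; fry adjusted p = 0.0020). Ddit4, an inhibitor of mTOR signalling, rose from 8.13 to 10.14 (adjusted p = 0.00095), the prolyl hydroxylase Egln3 from 6.45 to 8.44 (adjusted p = 0.0051; 1.21 by its other probe set), hexokinase Hk2 from 8.60 to 10.21 (adjusted p = 0.0033) and the vasoactive peptide Adm from 7.02 to 8.62 (adjusted p = 0.0164). The list median lay 0.54, 0.93 and 0.54 above the wild type mean in the 3 Norrin pools, against -0.08 to 0.11 in wild type.

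Stress and interferon genes rose too, on fewer members. Of 17 stress genes 3 rose, 4 adjusted over the list alone: the immediate early genes Jun (2.09; 1.25 by its other probe set), Egr1 (2.03) and Ier3 (1.68). The stress list had a median of 0.34 (camera adjusted p = 8.7e-05; adjusted p = 0.230 with an estimated correlation), and without Norrin E10.5 replicate 2 its camera adjusted p was 0.088. In that pool, which also had the highest hypoxia median, the heat shock genes Hspa1a and Hspa1b lay at 11.06 and 12.14 and Fos at 10.80. The other 5 E10.5 pools ran from 6.43 to 7.61, 7.69 to 10.50 and 8.97 to 9.35. Of 8 interferon genes Ifit1 (2.17) and Cxcl10 (0.81) rose, 5 adjusted over the list alone (median 0.64, camera adjusted p = 6.9e-06; adjusted p = 0.153 with an estimated correlation). Of 10 p53 targets 0 passed by limma over all genes, 3 at an unadjusted p under 0.05 and 2 adjusted over the list alone (median 0.22, camera adjusted p = 0.0215; adjusted p = 0.108 with an estimated correlation; 0.110 by preset camera without Norrin E10.5 replicate 2). Cholesterol synthesis genes were lower: 1 of 14 fell, Lss (-0.95, adjusted p = 0.0451; -0.87 and -0.24 by its other probe sets), 6 adjusted over the list alone, with a median of -0.47 (camera adjusted p = 5.7e-06; adjusted p = 0.153 with an estimated correlation). Proliferation genes had a median of -0.09, with 0 of 21 past the threshold by limma and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.292).

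Wnt genes were higher at E10.5. Of 30 pathway components 4 rose, 7 adjusted over the list alone, with a median of 0.18 (camera adjusted p = 5.7e-05; adjusted p = 0.0515 with an estimated correlation). Frzb rose from 6.28 to 8.63 (adjusted p = 7.9e-05), and the receptors Fzd6, Fzd2 and Fzd7 rose by 0.94, 0.84 and 0.77. Other probe sets of Fzd6 gave 0.65 and -0.05. Of 19 beta-catenin targets 1 rose, 4 adjusted over the list alone, with a median of 0.24 (camera adjusted p = 0.00016; adjusted p = 0.108 with an estimated correlation). That gene was Dkk1, from 6.03 to 7.82 (adjusted p = 0.0033; 1.06 by its other probe set). Apcdd1, a target and Wnt inhibitor, had an effect of 0.94 (adjusted p = 0.0579; 0.0021 with the block), and Znrf3 and Cdx2 had 0.73 and 0.57.

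**Figure D2:**
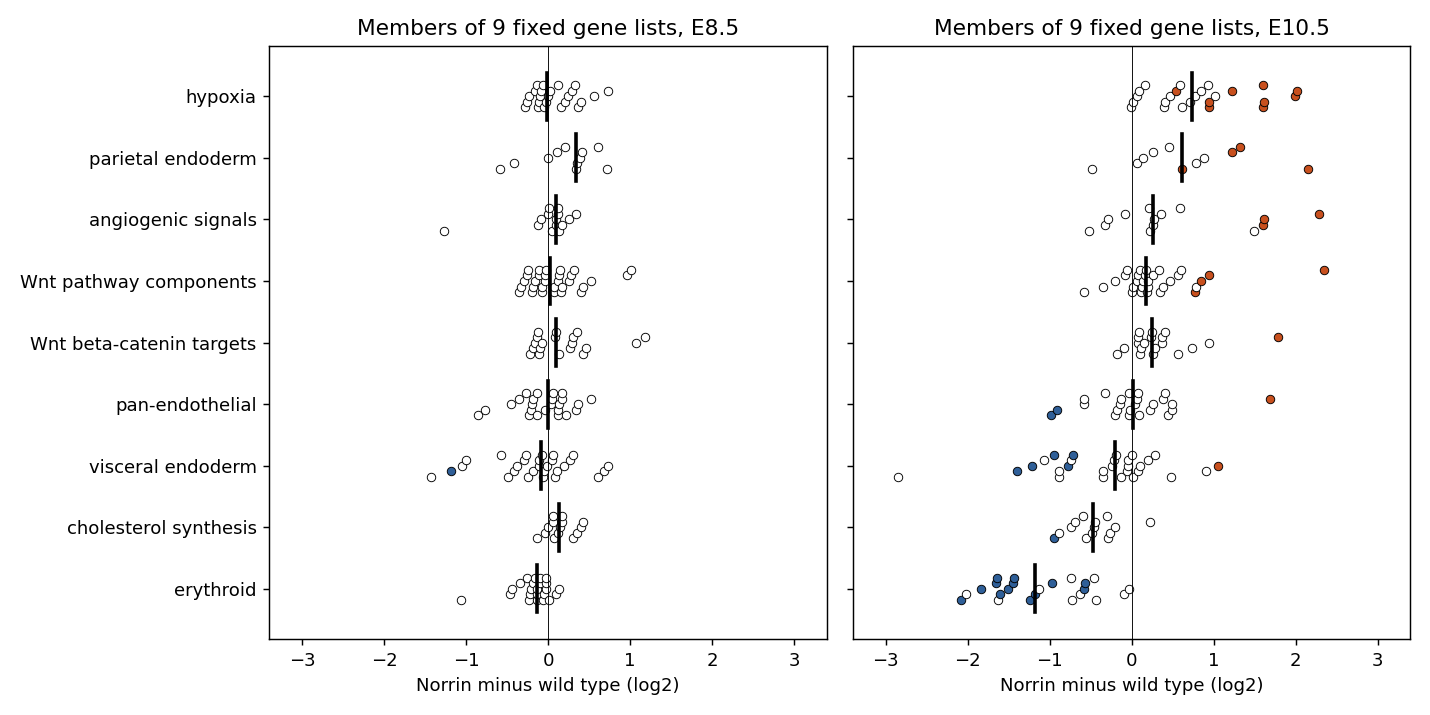
Norrin minus wild type difference (log2) of each measured member of 9 fixed lists at E8.5 and E10.5; filled points passed the adjusted threshold (orange higher, blue lower) and black bars mark list medians. The erythroid median was -1.17 at E10.5 and -0.13 at E8.5, and the hypoxia median at E10.5 was 0.74.

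The pan-endothelial, barrier, arterial and venous lists were not called, while single members of the first 3 passed. Of 24 pan-endothelial genes 1 rose, the VEGF receptor Flt1 (8.57 to 10.26, adjusted p = 2.9e-05; 1.13 to 1.85 by its 3 other probe sets), and 2 fell, the diaphragm protein Plvap (-0.99) and von Willebrand factor Vwf (-0.92); the median was 0.01, turned to -0.01 under each of 3 other scalings (camera adjusted p = 0.734). Of 15 barrier endothelial genes, some of which Norrin controls in retinal vessels, 2 rose and 4 fell. The list sets no direction for its members, so its median and camera test do not read a barrier response. Sox17 and the glucose transporter Slc2a1 (0.95) rose, and Abcb1a, the amino acid transporter Slc38a5 (-1.55, adjusted p = 0.037), the transferrin receptor Tfrc (-0.93) and Plvap fell; the median was 0.28 (camera adjusted p = 0.283). Of 19 arterial and Notch genes Sox17 and the ephrin Efnb2 (0.62; 0.30 to 0.58 by its 3 others) rose and the connexin Gja4 (-1.03) fell; the median was -0.03 and the mean 0.10 (camera adjusted p = 0.832). Of 8 venous and lymphatic genes 0 passed by limma, with 0 at an unadjusted p under 0.05 (median -0.07, camera adjusted p = 0.633). Angiogenic signals were higher, with 3 of 14 past the threshold and 5 adjusted over the list alone: the matrix proteins Ccn2 (2.28) and Ccn1 (1.62), and Adm (median 0.26, camera adjusted p = 0.00093; adjusted p = 0.108 with an estimated correlation). Of 12 smooth muscle genes Tagln (1.42) and Acta2 (0.54; 0.16 and 0.38 by its others) rose (median 0.26, camera adjusted p = 0.0108; adjusted p = 0.206 with an estimated correlation; 0.096 by preset camera without Norrin E10.5 replicate 2). Of 16 mesenchyme genes Pdgfra rose (9.42 to 11.32), and 7 did with the block (median 0.30, camera adjusted p = 0.0016; adjusted p = 0.108 with an estimated correlation). Of 10 BMP and TGF-beta targets Tgfbi rose (1.41; median 0.17, camera adjusted p = 0.163).

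Visceral endoderm genes were lower and parietal endoderm genes higher. Whether the Norrin pools carried along more parietal endoderm was not tested. Of 28 visceral endoderm genes 1 rose and 5 fell, or 2 and 9 adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.000765; adjusted p = 0.159 with an estimated correlation). The apolipoproteins Apom and Apoc2 fell by 1.40 and 1.22. Albumin (Alb) had an effect of -2.85 that did not pass (adjusted p = 0.0675; 0.0061 with the block). The wild type pools lay at 8.82, 12.85 and 9.06, and without the second of them the effect was -1.55 (adjusted p = 0.012). Of 11 parietal endoderm genes 4 rose, 6 adjusted over the list alone, with a median of 0.62 (camera adjusted p = 8.4e-07; adjusted p = 0.052 with an estimated correlation). They included the plasminogen activator Plat (8.11 to 10.26; -0.05 by its other probe set), Srgn (1.33) and the basement membrane collagen Col4a2 (11.55 to 12.77).

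Markers of neighbouring tissues were uneven between pools. Trophoblast genes had a median effect of 0.70 with 0 of 10 past the threshold by limma, 1 at an unadjusted p under 0.05 and 1 adjusted over the list alone (camera adjusted p = 0.0260; adjusted p = 0.465 with an estimated correlation; 0.0911 with the block). In Norrin E10.5 replicate 2 they lay 2.65 above the wild type mean, and in the other 5 pools between -0.27 and 0.14; without that pool the list turned downward (camera adjusted p = 0.635). Of 7 decidua genes Wnt4 rose (1.00; 0.39 by its other probe set; median 0.39, camera adjusted p = 0.0154; adjusted p = 0.206 with an estimated correlation; 0.0536 by preset camera without wild type E10.5 replicate 1). The decidual prolactin Prl8a2 lay at 9.84, 7.24 and 10.23 in the 3 Norrin pools and at 6.98, 7.70 and 7.55 in wild type (adjusted p = 0.26), and with it as a covariate 213 genes passed. Embryo neural genes were not called (median 0.06, 0 of 12 by limma, 2 at an unadjusted p under 0.05, camera adjusted p = 0.620). The 3 Y-linked genes averaged 4.79 in Norrin E10.5 replicate 2 and 6.87 to 8.21 in the other 5 pools, and 0 of the 4 sex-linked genes passed at either stage by limma, with 0 at an unadjusted p under 0.05. Xist lay at 7.94 in wild type E10.5 replicate 2 and at 10.34 to 11.68 in the other 5 pools. The labels give mixed sex, but by these values the share of each sex differed between pools, also between the same-numbered E10.5 pools 2. Without both pools of Norrin number 2, 481 genes passed at E10.5 and 1 at E8.5.

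**Figure D3:**
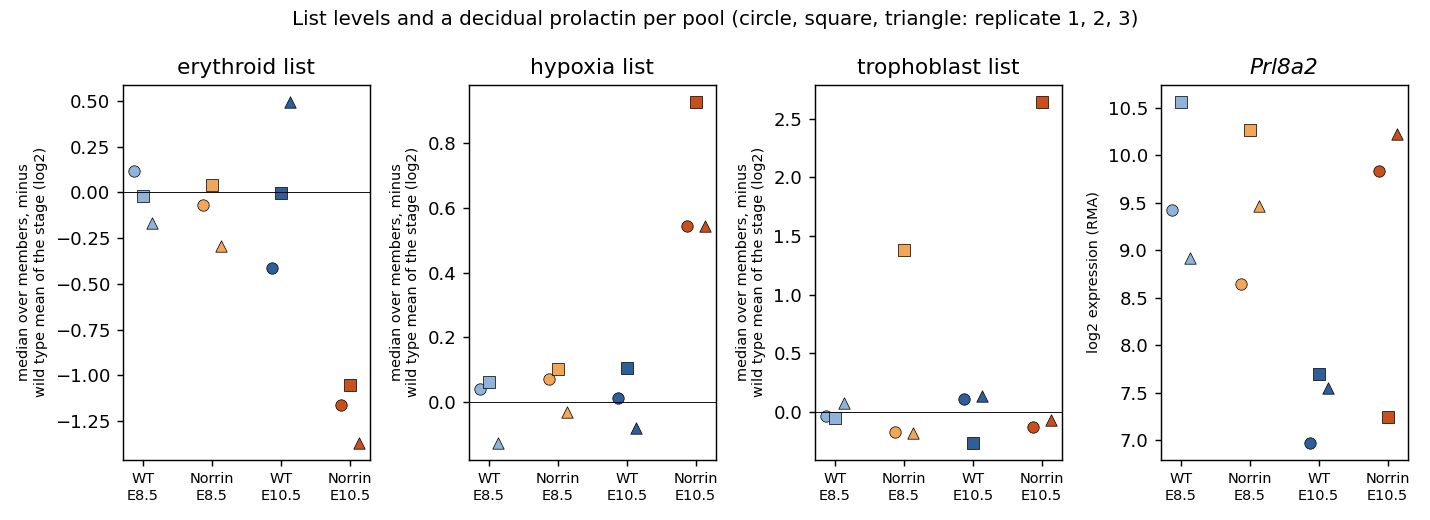
Median over the erythroid, hypoxia and trophoblast lists in each pool, relative to the wild type mean of the stage (log2), and the log2 level of Prl8a2, with 3 pools per group. The trophoblast median was 1.38 and 2.65 in Norrin replicate 2 at E8.5 and E10.5, while the erythroid and hypoxia medians lay outside the wild type range in all 3 Norrin pools at E10.5.

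The Norrin effects at E8.5 and E10.5 were compared. Their means came from separate arrays, but the spread of each gene was estimated from the arrays of both stages together. Of the 14 genes called at E8.5, 10 were called at E10.5 too, all in the same direction: Cpm, Cyp26a1, Flrt3, Nefl, Prom1, Scube2, Sox17 and Zfp703 higher and Apoa4 and Slc22a2 lower. Independent lists would share 0.185 higher and 0.0888 lower genes (Fisher's exact p = 5.6e-13 and 0.0029). The lists were not independent, since a gene with a low shared spread is more easily called at both stages. Fisher's test also treats genes as independent, so these p-values do not measure how far the stages agree. A fit to the 6 E8.5 arrays alone called 0 genes, so the overlap could not be read with separate spreads. All 14 had the same sign at E10.5, and of the 741 genes called at E10.5, 602 (81.2%) had the same sign at E8.5. Across all genes, which are not independent replicates, the effects correlated with Pearson's r = 0.414 and Spearman's rho = 0.294. With replicate number as a block within each stage, 157 genes were called at both stages, 153 in the same direction.

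**Figure D4:**
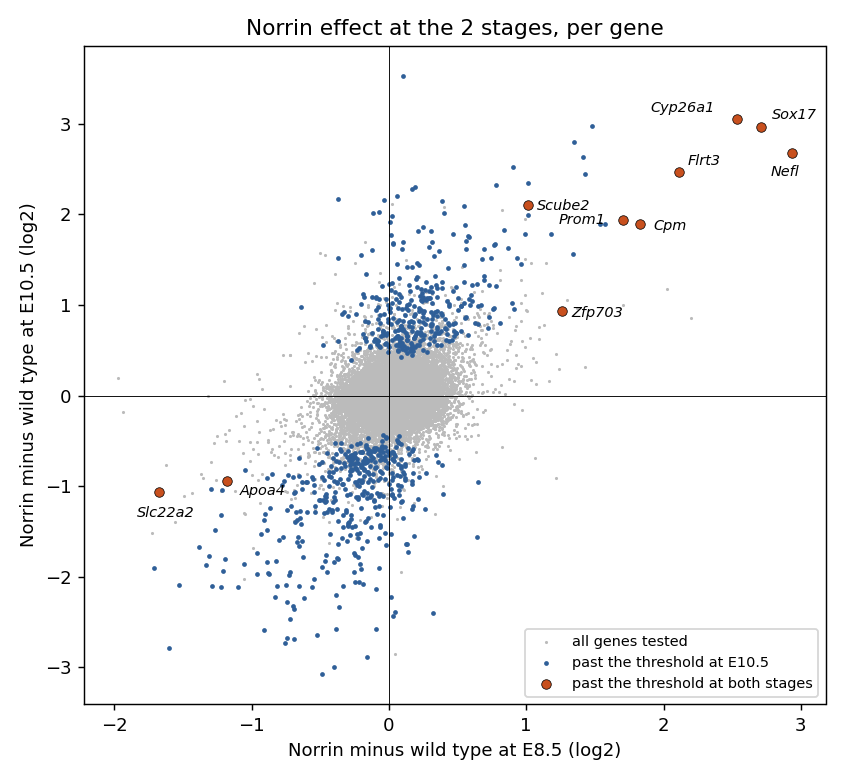
Norrin minus wild type difference (log2) at E8.5 against that at E10.5 for 18193 genes; blue points passed the threshold at E10.5 and the 10 labelled orange points passed at both stages. All 10 labelled genes lie in the quadrants of equal sign.

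The difference between the effects was tested as an interaction. Flt1 responded at E10.5 (1.69) and had an effect of 0.03 at E8.5, a difference of 1.65 (adjusted p = 0.0030). Saa4, Fbp2 and Abcb1a fell at E10.5 with differences of -2.72, -2.59 and -1.99, and each rose between the stages in wild type, by 2.55, 1.98 and 2.56. Slc16a7, a monocarboxylate transporter, and Vldlr passed too (-2.48 and 2.15). Their E8.5 pools lay near the floor (3.72 to 4.03 and 4.15 to 4.64), where no Norrin effect could be read, so these 2 values hold the E10.5 effect and are no measured difference. Limma called 17 genes, 7 with a higher and 10 with a lower effect at E10.5, and 1275 had an unadjusted p under 0.05. The other named genes were Kif5c (2.13), Adamts1 (1.62) and Rhob (1.24), and Rasgrp2 (-1.97), Pnp (-1.54), Nqo2 (-1.20), Misp (-1.19) and Cpt2 (-1.05). The 3 other probe sets of Kif5c gave 0.06 to 0.41, the 5 others of Vldlr 0.28 to 2.61, the 3 others of Rasgrp2 -1.93 to -0.36, the 2 others of Nqo2 -1.23 and -0.80, and the others of Saa4 and Cpt2 -1.46 and -0.34. With the block within each stage 376 genes passed, 149 higher and 227 lower, all 17 among them, and with array weights 2728. Of 100 splits of the arrays within the stages, 7 gave 17 or more, the real one included.

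By preset camera 11 of 26 lists differed between the stages, 8 with a higher and 3 with a lower effect at E10.5. With the block within each stage 12 passed. None of the 11 held with an estimated correlation or by fry (0 lists each). The median difference was -0.96 for erythroid genes (camera adjusted p = 7.0e-15; adjusted p = 0.180 with an estimated correlation), 0.69 for hypoxia (camera adjusted p = 2.4e-13; adjusted p = 0.180 with an estimated correlation) and -0.60 for cholesterol synthesis (camera adjusted p = 2.5e-08; adjusted p = 0.180 with an estimated correlation). By limma 0 erythroid and 0 hypoxia genes passed the interaction test over all genes; 14 and 16 had an unadjusted p under 0.05, and 14 and 10 passed adjusted over the list alone.

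Far more genes differed between E8.5 and E10.5 than between genotypes. Each stage was normalized in its own run, so stage and run cannot be told apart in these contrasts. In wild type, limma called 5915 genes, 4619 higher and 1296 lower at E10.5, with 1430 changing at least 2-fold (1306 higher, 124 lower), and with array weights 10797 passed. Kng1, the precursor of plasma kinins, went from 6.46 ± 1.00 to 11.42 ± 0.75, and Serpina1c, a plasma protease inhibitor, from 6.68 ± 0.35 to 11.11 ± 0.69 (SD, n = 3). Alb rose by 3.96 (2.66 without wild type E10.5 replicate 2) and the glycogen phosphorylase Pygl by 3.96. Mgst1 rose by 4.11 (3.01 without that pool, -0.21 by its other probe set) and Plekhd1 by 3.86. Slc16a7, the complement protein C1qb, the platelet chemokine Ppbp and Atp8b1 started near the floor in wild type E8.5, at 3.99, 4.32, 4.75 and 3.87. Their rises read 5.06 (adjusted p = 1.2e-08), 4.26, 4.15 and 3.86 (2.96 without wild type E10.5 replicate 2), and the floor may hide part of each.

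Genes lower at E10.5 in wild type included Zfp934 (-3.10; -1.07 by its other probe set), Emb (-2.77, or -1.93 without wild type E10.5 replicate 2), the cytokine receptor chains Csf2rb2 (-2.31) and Csf2rb (-2.18), the placental and decidual prolactins Prl8a2 (-2.23) and Prl4a1 (-2.13), the homeobox gene Hoxb6 (-2.11), the BMP target Id3 (-1.90), Phlda1 (-1.79) and the DNA methyltransferase Dnmt3b (-1.72; -1.14 by its other probe set). The median gene was 0.14 higher at E10.5 as deposited, and -0.05, -0.16 and -0.00 after quantile normalization, median centring and cyclic loess. Higher genes made up 78.1% of the calls as deposited and 46.3%, 32.7% and 53.8% in those scalings, so the split rests on the scaling; the 20 named genes passed in the same direction in all 3.

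Cholesterol synthesis genes rose in wild type, 14 of 14 measured, with a median of 1.54 against 0.14 for all genes (camera adjusted p = 1.4e-07; adjusted p = 0.717 with an estimated correlation), and 14 of 14 in each other scaling. Macrophage and myeloid genes rose in 16 of 19 (median 1.17, camera adjusted p = 4.5e-06; adjusted p = 0.717 with an estimated correlation), and in 11 under the other scalings. Interferon genes rose in 6 of 8 (median 0.94, camera adjusted p = 0.0109) and smooth muscle genes in 8 of 12 (median 0.69, camera adjusted p = 0.0251). Proliferation genes fell in 5 of 21 (median -0.23, camera adjusted p = 0.0025), and pan-endothelial genes rose in 2 and fell in 4 of 24 (median -0.27, camera adjusted p = 0.0251). These 4 lists also had an adjusted p of 0.717 with an estimated correlation, and their medians kept their sign in the other scalings, where 4 interferon and 5 to 8 smooth muscle genes rose and 5 to 9 proliferation and 5 to 9 pan-endothelial genes fell.

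Norrin yolk sacs were compared between the stages in the same way. Cebpa rose by 3.51 with stage in wild type and by 0.92 in Norrin; the difference between these changes had an adjusted p of 0.0678. Erythroid genes fell in 13 of 23 (median -0.64 against 0.15 for all genes, camera adjusted p = 1.9e-08; adjusted p = 0.331 with an estimated correlation), and hypoxia genes rose in 17 and fell in 1 of 24 (median 1.01, camera adjusted p = 9.9e-05; adjusted p = 0.331 with an estimated correlation). In Norrin yolk sacs 6895 genes changed between the stages, 5133 higher and 1762 lower, with 1649 changing at least 2-fold (1426 higher, 223 lower), and with array weights 11639 passed. By camera 11 of 26 lists passed (9 up, 2 down), 0 with an estimated correlation and 18 by fry. Higher genes made up 74.4% of the calls as deposited and 46.0%, 28.3% and 52.2% after quantile normalization, median centring and cyclic loess.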

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

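The splits of the arrays were set before the data were examined; the tests of dilution, normalization, fewer erythroid cells, trophoblast, decidua and loss of erythroid RNA were chosen after the results were seen.

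The effect of Norrin differed between the stages by limma's interaction test for 14 named genes. The effect at E10.5 exceeded that at E8.5 by 2.148 (log2) for Vldlr, 2.134 for Kif5c, 1.654 for Flt1, 1.616 for Adamts1 and 1.237 for Rhob. It lay below that at E8.5 for Saa4 (-2.718), Fbp2 (-2.588), Slc16a7 (-2.476), Abcb1a (-1.992), Rasgrp2 (-1.967), Pnp (-1.535), Nqo2 (-1.205), Misp (-1.187) and Cpt2 (-1.048). Vldlr and Slc16a7 lay near the floor in all E8.5 pools, so their values hold the E10.5 effect alone. Saa4 and Abcb1a lay at E8.5 near the levels they fell to in Norrin E10.5, so a fall of that size may not have been readable there. Of 100 splits drawn from 200 within the stages, 7 gave 17 genes or more, the real one included, and the highest other gave 593, so chance is not excluded for this count. Of the 6 others, 5 kept the genotypes apart at E10.5 and mixed them at E8.5 (highest 229), so their counts include the E10.5 effect of Norrin by construction; the other, with 593, mixed both. The 593 therefore points to a structure of the arrays other than genotype. Among the 32 splits that part all same-numbered pools, 6 gave 17 or more, the real one included (highest 643), and with replicate number as a block within each stage 3 of 32 gave 376 or more (highest 2465). All of these kept the genotypes apart at E10.5 and so hold the E10.5 effect as well; the 24 that mixed the genotypes at E10.5 gave 0 in either fit.

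By preset camera the effect differed between the stages for 11 lists, and for none of them with an estimated correlation (adjusted p from 0.18 to 0.501) or by fry. The median difference was 0.1615 for Wnt pathway components, 0.1958 for angiogenic signals, 0.3019 for smooth muscle, 0.2018 for parietal endoderm, 0.4721 for decidua, 0.6851 for hypoxia, 0.5683 for stress and 0.7967 for interferon. It was -0.9645 for erythroid, -0.1483 for proliferation and -0.604 for cholesterol synthesis.

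Probe sets with no or several gene names, left out of the gene tests above, were tested in a fit of all probe sets. At E10.5, 86 of 10092 (0.852%) passed by limma, 50 higher and 36 lower, against 2.66% of the named probe sets in that fit. At E8.5, 0 passed by limma and 574 had an unadjusted p under 0.05.

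Too few splits exist within a stage or genotype for a share under 0.05. At E8.5, 2 of 10 splits gave 14 genes or more, the real one included. The highest other, 750, set wild type replicates 1 and 2 with Norrin replicate 1 against the rest, which points to a structure of these arrays other than genotype. In the 4 splits parting all same-numbered pools, the highest other was 0, and with the block within the stage it was 0 against 257. At E10.5 only the real split, 1 of 10, gave 741 genes, and the highest other gave 0, as with the block (0 against 2400). For the change with stage it was likewise 1 of 10 in wild type (5915, highest other 0) and 1 of 10 in Norrin (6895, highest other 0), but each stage was normalized in its own run, so stage and run cannot be told apart.

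Erythroid genes were lower in each Norrin pool at E10.5. Dilution by trophoblast or decidua is argued against as the only cause. The visceral endoderm median lay at least 0.8857 (log2) above the erythroid median in every Norrin pool and the pan-endothelial median at least 0.712. The visceral endoderm list was itself lower, so a part from dilution stays open. The erythroid median was -1.197 to -1.276 under 3 other scalings. These were applied to values that RMA had already quantile-normalized within the stage. They cannot undo that step, so they do not decide on the authors' normalization. Fewer erythroid cells, from the genotype or from blood lost at dissection, may account for it. The median of Hbb-bh1, Hbb-y and Hba-x fell by 0.7677 less than that of the other erythroid genes, the globin Hba-a1 (-0.04) among these. At the top of the scale, where the first 3 lay (14.43 to 14.61 in wild type), this gap decides nothing. Lower transcription per erythroid cell stays open too and was not tested.

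Hypoxia genes were higher in each Norrin pool at E10.5. Trophoblast as the only source is argued against. The hypoxia median was at least 0.5428 in the 2 Norrin pools whose trophoblast genes lay within the wild type range, against 0.105 in the highest wild type pool. However, Prl8a2 lay at 9.84 and 10.23 in these 2 pools, above wild type (6.98 to 7.70). No Norrin pool lay within the wild type range for both markers, so tissue of either kind carried along stays open. With Prl8a2 as a covariate the hypoxia median was 0.9162 (camera adjusted p = 3.9e-20, or 0.0624 with an estimated correlation). This does not decide on decidua. Prl8a2 varied most within a group among the Norrin E10.5 pools. Its lowest value there (7.24, replicate 2) fell in the pool with the trophoblast markers and the highest hypoxia median. A larger share of all other RNA after loss of erythroid RNA is argued against only as the sole change. The hypoxia median exceeded the visceral endoderm and pan-endothelial medians by at least 0.3126 in every Norrin pool. Neither of these lists rose, and the visceral endoderm list was itself lower. Parietal endoderm genes, not used in this test, did rise, so a part from a larger share stays open. The immediate early genes Jun, Egr1 and Ier3, which handling can raise, were higher in every Norrin pool as well (2.09, 2.03 and 1.68). Other such genes were uneven: Fos (0.64), Atf3 (0.45), Dusp1 (0.31) and Hspa1b (0.09) did not pass. In Norrin replicate 1 Fos (8.97) and Hspa1b (7.69) lay below all wild type pools. Fos lay above all of them in Norrin replicates 2 (10.80) and 3 (9.35), as did Hspa1b in replicate 2 (12.14). Time from dissection to lysis was not recorded in the labels and stays open, as does tissue carried along. A response to low oxygen in Norrin yolk sacs may remain beside them as a hypothesis, found and tested on the same data. No test here decides between these explanations.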

How the results depend on the processing

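The block within each stage, the exclusion of both Norrin pools numbered 2 and the covariates were chosen after seeing the data; the other alternatives were set beforehand. No named gene past the threshold reversed under any alternative. Named genes numbered 13 at E8.5, 58 at E10.5, 14 for the interaction and 20 for stage in wild type. The array weights and the block within the stage kept all they were run on. Both called more genes in every contrast (counts below), so that says little. Quantile normalization kept 11, 56, 13 and 20, and the floor at the 25th percentile kept 2, 43, 5 and 17. Within a stage the genes called at E8.5 rest on the spread taken from all 12 arrays. The cause was not tested for any shift below, except that fewer genes, arrays or degrees of freedom entered some settings by construction.

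Norrin at E8.5 (14 genes): floored values gave 4, trended robust spread 22, array weights 5147, only the 6 arrays compared 0 by limma (951 at an unadjusted p under 0.05), the replicate block 5, the block within each stage 257 and both Norrin number 2 pools left out 1. With 1 array left out the count ran from 1 to 20: it was 1 without Norrin E8.5 replicate 2, 2 without wild type E8.5 replicate 1, 6 without replicate 3 and 8 without wild type E10.5 replicate 3. Prom1 passed in all of these, and each other named gene was lost in 1 to 10 of the 12.

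Norrin at E10.5 (741): dim genes left out gave 472, array weights 2316, a 2-fold threshold 333, the block within each stage 2400, the number 2 pools left out 481 and Prl8a2 as covariate 213. With 1 array left out it was 353 to 894: 353 without Norrin E10.5 replicate 3, 410 without replicate 1, and 435 and 477 without wild type E10.5 replicates 2 and 3. Igfbp1 was lost in 8 of 12, Slc38a5 and Efnb2 in 7, Lss and Itga2b in 10.

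Interaction (17): dim genes left out gave 3, all probe sets 29, the mean of a gene's probe sets 37, quantile normalization 29, floored values 10, array weights 2728, the block within each stage 376, Prl8a2 7 and Y-linked genes 8. With 1 array left out it was 5 to 36: 5 without wild type E8.5 replicate 2 or wild type E10.5 replicate 1, 6 without wild type E8.5 replicate 1, Norrin E8.5 replicate 1 or Norrin E10.5 replicate 3, 7 without wild type E10.5 replicate 2, 9 without Norrin E8.5 replicate 2, 31 without Norrin E10.5 replicate 2 and 36 without wild type E8.5 replicate 3.

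Stage in wild type (5915): dim genes left out 1918, all probe sets 15161, array weights 10797, 2-fold 1430 and Prl8a2 2525; with 1 array left out 4311 to 6285. Stage in Norrin (6895): 2641, 17281, 11639 and 1649 in the same settings up to 2-fold, and 3853 without the number 2 pools; with 1 array left out 5242 to 7629.

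Gene lists: at E10.5 (16) an estimated inter-gene correlation gave 0, and leaving out 1 array 13 to 17. Over these arrays the camera adjusted p ran from 3.1e-08 to 0.0876 for stress, 0.0028 to 0.0960 for smooth muscle and 0.0119 to 0.110 for p53 targets (each highest without Norrin E10.5 replicate 2), from 0.0031 to 0.0536 for decidua (highest without wild type E10.5 replicate 1) and from 0.0025 to 0.352 for megakaryocyte genes (highest without Norrin E10.5 replicate 1). At E8.5 (0) cyclic loess gave 4, the replicate block 2, the block within each stage 2, the number 2 pools left out 5, and the trophoblast, Prl8a2 and Y-linked covariates 4 each; leaving out 1 array gave 0 to 7. For the interaction (11) an estimated correlation gave 0 and fry 0, the block within each stage 12, and leaving out 1 array 8 to 14.

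Reversed, none of them past the threshold as reported except the trophoblast list: that list at E10.5 had an adjusted p of 0.673 without the number 2 pools and 0.00034 to 0.635 with 1 array left out. Without the number 2 pools the E10.5 effect was -0.27 for Ctsq, 0.0223 for Fzd4, -0.0928 for Hspa1a, -0.0287 for Ndp and -0.17 for Tspan12, and the E8.5 effect of Tpbpa was -0.0215. With 1 array left out, E10.5 effects ran from -0.27 to 1.72 (Ctsq), -0.17 to 0.0223 (Fzd4), -0.0928 to 2.22 (Hspa1a), -0.0172 to 0.79 (Id3), -0.0287 to 0.0339 (Ndp) and -0.17 to 0.41 (Tspan12), and E8.5 effects from -0.13 to 0.35 (Fzd4), -0.12 to 0.13 (Lrp5), -0.58 to 0.29 (Prl8a2), -0.0215 to 0.80 (Tpbpa) and -0.29 to 0.43 (Tspan12). With array weights the E8.5 effects were 0.18 (Jag1), 0.17 (Lrp5) and -0.20 (Tspan12). Median centring gave 0.0116 for Lrp5 at E8.5 and -0.0220 for Ndp at E10.5, the mean of probe sets 0.0669 for Fzd4 at E10.5, and quantile normalization and cyclic loess 0.0282 and 0.0261 for Ndp at E8.5. The Prl8a2 covariate gave 0.0688 for Lrp6 and -0.00209 for Ndp at E10.5. The trophoblast covariate gave -0.0309 for Ndp and -0.10 for Tspan12. The Y-linked covariate gave -0.00756 for Ndp and -0.0408 for Tspan12 at E10.5, and 0.91 for Prl8a2, -0.91 for Tpbpa and -0.0821 for Tspan12 at E8.5.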

Other observations

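The covariance test of delayed maturation was set before its result was seen; the genes in the next paragraph, and the sets chosen on 1 wild type pool, were chosen after values were seen.

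Single members of the erythroid list that fell at E10.5 included the haem synthesis enzymes Alas2 and Fech, by 1.64 and 0.98, and the membrane proteins Epb42 and Kel, by 1.51 and 1.43. Among visceral endoderm genes the transcription factor Hnf4a fell by 0.71 and the secreted signal Ihh rose by 1.05 (limma).

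Delayed maturation of the Norrin yolk sac was tested across all genes. The covariance across genes of the Norrin effect at E10.5 with the wild type change was -0.0498, against -0.0193 simulated from the shared wild type arrays (200 simulations), a difference of -0.0305 (-0.0469 to -0.0039 with 1 array left out). That difference is consistent with a partial delay, with a slope of -0.114 on the wild type change. With the change in Norrin, part of which is shared by construction, the covariance less its simulated part was 0.0230. The simulated arrays were independent, without the pairing of same-numbered pools seen within a stage. Genes were also chosen as at least 2-fold changed in 1 wild type E10.5 pool, and the Norrin effect was read from the pools of the other replicates. Its median, less that of all genes, was -0.11, -0.09 and -0.10 for rising genes and 0.10, -0.00 and 0.15 for falling genes. A partial delay stays a hypothesis on the covariance of -0.0305; fewer cells of the types that carry the rising genes were not tested against it.

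The list of 10 trophoblast genes shares 0 genes with other lists, and 2 of them reached the median gene level in wild type pools; of the 7 decidua genes 0 are shared and 3 reached it. The trophoblast median of Norrin replicate 2 lay 1.38 above the wild type mean at E8.5 and 2.65 at E10.5. Array weights estimated by limma ran from 0.219 for wild type E8.5 replicate 3 to 8.03 for Norrin E8.5 replicate 2.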
